A study of Arabidopsis thaliana with 8 samples.

How the data were processed

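Total RNA of Arabidopsis thaliana, ecotype Columbia-0, was measured on 8 one-colour arrays, 2 biological replicates in each of 4 groups, per the labels. Per the labels' protocols, seeds were held at 4 °C for 3 days and then grown on agar plates at 22 °C with 16 h of light and 8 h of darkness. RNA was taken up in TRIzol and cleaned on columns with DNase, and 500 ng was amplified from an oligo(dT) primer into Cy3-labelled cRNA. The polysome fractions named in the series title are not used here.

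Per the file headers, the arrays are Agilent design 021169, read with Feature Extraction 10.10.1.1 under protocol GE1_1010_Sep10, on a grid annotated with build TAIR10. The deposited scanner files hold intensity values in linear units, with no scaling between arrays: the processed signal is background-subtracted and detrended within an array, and the median spot signal and the median local background are given raw. The deposited value table also holds intensity in linear units. Within each array it equals the processed signal times 1 factor, from 2.08 to 4.44 across the arrays, and it is empty where a spot was not well above background. The basis of that factor is not stated in the submitters' processing notes, so the table served only as an alternative source of values.

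Each array has 45220 spots, of which 43803 are not controls. They carry 43603 different probes, and 34392 of these have a locus in the annotation, covering 25426 loci. Spots marked as outliers by the scanner software, from 5 to 13 per array, were left out, and no spot was saturated (0 on each array). The processed signal was averaged over repeated spots of a probe, its log2 was taken, and the 75th percentile of the non-control probes of the array was subtracted. A probe was kept if it was well above background on both arrays of at least 1 group, and the brightest such probe stood for its locus. This left 20629 genes. Probes without a locus were fitted separately. No coordinates are given, because the gene table at hand follows a later release than the grid file.

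One linear model with a mean per group was fitted across all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with 4 residual and 1.90 prior degrees of freedom. Genes past a Benjamini-Hochberg adjusted p of 0.05 over all genes tested are called changed. The 2 comparisons named in the design text are the 21-day aerial part against the 2-day whole plant, and mature against young leaves. A secondary contrast sets the 21-day aerial part against the mean of both leaf classes. Standard errors after the ± sign come from this fit, and n is 2 arrays per group throughout. Where a gene was not well above background on either array of a group, its fold is a lower bound, taken against the larger of its signal there and the lowest signal called well above background on that array, and written as at least N-fold. The bound uses the mean of the brighter group, so it allows for low signal and not for the spread between replicates. The number of arrays limits the precision: the median standard error was 0.11 on the log2 scale in both main comparisons.

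Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The same test with the correlation estimated for each list, and limma's fry, stand beside it. There were 23 lists with 483 members, of which 474 were kept, 3 were not on the array and 6 had a symbol that the tables pair with another locus. The lists cover photosynthesis, chlorophyll synthesis, plastid and cytosolic ribosomal proteins, the cell cycle, meristem and leaf growth, wall expansion, the secondary wall, seed maturation, lipid mobilisation, root markers, floral identity, flowering time, the stomatal lineage, guard cells, senescence, salicylate defence, jasmonate, glucosinolates, flavonoids, the clock, and plastid-encoded and mitochondrion-encoded genes. The organelle-encoded lists matched 0 loci. Guard cells kept 4 tested members, under the minimum of 5, and were not tested.

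The fits, the lists, the alternatives planned for them and the rule for named genes were fixed before the data were examined. That rule takes, for each main comparison, the 5 largest rises and 5 largest falls among changed genes detected on all arrays compared, the largest lower bound in each direction, the 2 most changed members of each list past the camera threshold, and a fixed set of genes whatever their result. It takes the 5 largest rises of the secondary contrast. Genes named outside it are said to be so. Spike-in scaling and a mean of linear signals were added as alternatives after seeing the data, as were short lists of iron-related and cold-regulated genes.

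Alternatives covered the background correction (normexp with offset 50), quantile and median scaling, the filter on dim probes, the mean over probes of a gene, the value table, the arrays in the fit, the variance model, a fold of at least 2 as well, and leaving out each array in turn. The deposited files have no mean spot signal, so normexp was run on the median signal and median local background in its place. The method was tested on simulated data with 200 changed genes among 20629, besides the cell cycle list, whose members were lowered by 1 on the log2 scale. For the age comparison 63% of 2-fold and 85% of 4-fold changes among the 200 were recovered, and 5.08% of calls were false. For the leaf comparison these shares were 69%, 90% and 2.15%. The simulated groups otherwise shared the same means, while 75.1% and 71.3% of genes were called in the age and leaf comparisons. The simulated shares therefore do not give the recovery or the false calls of the real comparisons. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.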

Results

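Transcript levels were measured in whole plants 2 days after germination, in the aerial part of plants 21 days after germination, and in young and mature leaves of plants of that later age. Per the labels, young leaves are the newer 3 leaves and mature leaves the older 3, without cotyledons. Each group has 2 arrays. Well above background were 74.6% of probes on both arrays of the 2-day plants, 72.4% and 72.1% in the 21-day aerial part, 69.7% and 69.2% in young leaves, and 66.7% on both arrays of mature leaves. Genes detected on both arrays numbered 20044, 19160, 18372 and 17700 in the same order. Replicates correlated across genes at 0.996, 0.995, 0.995 and 0.994, and genes are not independent replicates.

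The first comparison asks how the transcripts of the shoot at 21 days differ from those of the seedling at 2 days. The largest fall was that of ICL (AT3G21720, isocitrate lyase of the glyoxylate cycle), with a log2 fold change of -14.29 ± 0.36, and MLS (AT5G03860, malate synthase) had one of -10.74 ± 0.33. ICL was detected on both 21-day arrays, but its log2 level there, -6.64, was close to the lowest signal called well above background. Of the 17 genes of flowering time and phase change 13 rose and 4 fell, and SOC1 (AT2G45660) rose by 6.11 ± 0.09 on the log2 scale, a 68.9-fold increase. The photosynthesis list rose by a median of 1.01, while the lists of flavonoid synthesis, the cytosolic ribosome and the cell cycle fell. With an estimated correlation between genes these 4 calls and that of flowering time are lost (camera adjusted p = 0.382, 0.265, 0.340 and 0.320, and 0.265 for flowering time). The 2-day samples are whole plants, with roots, and the 21-day samples are labelled as the aerial part. Age and organ therefore differ together in every value of this comparison.

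In all, 7185 genes were higher and 8309 lower at 21 days (limma, 75.1% of 20629 tested). Of these, 3104 and 4361 changed at least 2-fold, and 312 and 900 at least 16-fold. The 2-fold counts were 2554 and 2271 with only probes well above background on all arrays, a filter that drops genes seen in 1 group alone, 2270 and 2776 with normexp background correction, and 2932 and 3003 with the value table. Among all genes tested, 376 were detected on both arrays at 21 days and on no array at 2 days, and the reverse held for 1148. With the arrays scaled on the spike-in probes, an alternative chosen after seeing the data, the split was 4406 higher and 9751 lower.

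The largest rises among genes detected in both groups were AT1G67865 (log2 fold change 10.03 ± 0.14), FRO7 (AT5G49740, a ferric reductase of the chloroplast, 9.15 ± 0.32), COR15A (AT2G42540, a cold-regulated chloroplast protein, 8.91 ± 0.52), AT2G39850 (8.67 ± 0.14) and FRO6 (AT5G49730, a ferric reductase, 8.27 ± 0.13). Next to ICL and MLS, the largest falls were those of AT4G36880 (-11.31 ± 0.14), AT5G17820 (-9.55 ± 0.63) and AGP3 (AT4G40090, an arabinogalactan protein, -8.94 ± 0.45). AT2G32870 was undetected at 2 days and at least 1430-fold higher at 21 days. AT5G44440 was undetected at 21 days and at least 3272-fold lower there.

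All 9 tested genes of floral identity rose, with a median log2 fold change of 4.55, or 4.31 with undetected genes at their bounds (camera adjusted p = 1.45e-04, and 0.320 with an estimated correlation). The list was written with 10 genes, and LFY did not pass the detection filter. SEP1 (AT5G15800) was at least 79.7-fold and AP1 (AT1G69120) at least 33.5-fold higher. Both were undetected at 2 days, and such genes pass the filter only through a later group, which favours rises. The rise of SEP1 is not particular to the aerial part, which stood at -0.56 ± 0.19 against young and 2.18 ± 0.19 against mature leaves. Of 17 genes of flowering time and vegetative phase change, 13 rose and 4 fell, with a median of 2.52 (camera adjusted p = 0.00146, and 0.265 with an estimated correlation). SPL3 (AT2G33810) was at least 303-fold, FUL (AT5G60910) at least 132-fold and the florigen gene FT (AT1G65480) at least 7.08-fold higher. SPL9 (AT2G42200) rose by 2.36 ± 0.11, and the floral repressor FLC (AT5G10140) fell, with a log2 fold change of -1.98 ± 0.10. The other 3 that fell were TSF, SMZ and SNZ, chosen for naming after their values were seen.

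Photosynthesis rose in 51 of 52 genes and fell in 1 (camera adjusted p = 4.56e-10, and 0.382 with an estimated correlation). LHCB2.1 (AT2G05100) rose by 1.78 ± 0.21 and PSBQ-2 (AT4G05180) by 1.77 ± 0.09. RBCS1A (AT1G67090, a small subunit of Rubisco) rose by 0.32 ± 0.08, a change that was -0.10 and not called under quantile normalization. Jasmonate synthesis and response rose in 11 of 15 genes and fell in 2, with a median of 1.88 (camera adjusted p = 0.00149, and 0.334 with an estimated correlation). JR2 (AT4G23600) was at least 490-fold and PDF1.2 (AT5G44420, a defensin) at least 72.9-fold higher. Glucosinolate synthesis rose in 17 of 23 genes and fell in 5, with a median of 0.68 (camera adjusted p = 0.00146, and 0.306 with an estimated correlation). Its regulator MYB29 (AT5G07690) rose by 4.03 ± 0.12, and MYB76 (AT5G07700) was at least 19.4-fold higher.

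Root markers fell in 24 of 26 genes and rose in 1, with a median of -5.51, or -5.34 at the bounds (camera adjusted p = 2.90e-08, and 0.265 with an estimated correlation). EXPA7 (AT1G12560) and EXPA18 (AT1G62980), expansins of root hairs, were at least 191-fold and at least 135-fold lower, and PYK10 (AT3G09260, a beta-glucosidase abundant in roots) had a log2 fold change of -4.64 ± 0.19. Seed maturation fell in 21 of 24 genes and rose in 1, with a median of -3.91, or -3.32 at the bounds (camera adjusted p = 1.45e-04, and 0.320 with an estimated correlation). The gene that rose was RAB18, named after its value was seen. The albumins SESA3 (AT4G27160), SESA5 (AT5G54740) and SESA4 (AT4G27170) were at least 58.4-fold, 44.6-fold and 17.7-fold lower, and near-identical family members can share signal. The cruciferin CRC (AT4G28520) had a log2 fold change of -2.26 ± 0.31 and was detected on 1 of 2 arrays at 21 days. Lipid mobilisation fell in 12 of 17 genes and rose in 3, with a median of -1.25 (camera adjusted p = 0.0133, and 0.265 with an estimated correlation).

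All 18 flavonoid genes fell, with a median of -3.32, or -3.11 at the bounds (camera adjusted p = 4.79e-07, and 0.265 with an estimated correlation). CHS (AT5G13930, chalcone synthase) had a log2 fold change of -4.33 ± 0.29 and its regulator MYB12 (AT2G47460) one of -4.32 ± 0.15. Every one of 41 genes of the cytosolic ribosome fell, with a median of -1.16 (camera adjusted p = 4.56e-10, and 0.340 with an estimated correlation). RPL3B (AT1G61580), RPL23AB (AT3G55280) and RPS6A (AT4G31700) had log2 fold changes of -1.71 ± 0.06, -1.60 ± 0.10 and -1.59 ± 0.08. The cell cycle list fell in 38 of 41 genes and rose in 0, with a median of -1.18 (camera adjusted p = 2.69e-07, and 0.320 with an estimated correlation). The Aurora kinase genes AUR2 (AT2G25880) and AUR1 (AT4G32830) had log2 fold changes of -2.21 ± 0.10 and -1.99 ± 0.08, the mitotic cyclin CYCB1;1 (AT4G37490) one of -1.58 ± 0.14, and PCNA1 (AT1G07370, the replication clamp) one of -1.47 ± 0.13.

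The stomatal lineage fell in 8 of 11 genes and rose in 1, with a median of -1.01 (camera adjusted p = 0.0449, and 0.382 with an estimated correlation). EPF2 (AT1G34245) had a log2 fold change of -2.36 ± 0.14 and BASL (AT5G60880) one of -1.79 ± 0.11. Plastid ribosomal proteins fell in 13 of 19 genes and rose in 0, with a median of -0.32 (camera adjusted p = 0.0391, and 0.644 with an estimated correlation). RPL35 (AT2G24090) had a log2 fold change of -0.62 ± 0.07 and RPL9 (AT3G44890) one of -0.60 ± 0.08. The plastid ribosome call was lost with quantile normalization, with median scaling, with only the arrays compared, without 2-day replicate 2 (median -0.21) and without 21-day replicate 1 (median -0.29). The stomatal call was lost with spike-in scaling, without either 2-day array (medians -1.04 and -0.98) and without 21-day replicate 1 (median -1.01).

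The other lists did not pass the camera test. Salicylate defence had 10 genes higher and 4 lower of 16 (median 1.17, or 1.02 at the bounds, adjusted p = 0.0851), and wall expansion 4 higher and 12 lower of 21 (median -0.48, adjusted p = 0.0769), lists that passed with spike-in scaling and with normexp, no filter or the value table, respectively. Meristem and leaf growth had 8 higher and 14 lower of 32 (median -0.31, adjusted p = 0.494). Senescence had 11 higher and 9 lower of 26 (median 0.03, adjusted p = 0.544), and chlorophyll synthesis 7 higher and 10 lower of 21. The median of the chlorophyll list was 0.01, while its mean of -0.07 and its camera direction were negative (adjusted p = 0.861). The secondary wall had 3 higher and 4 lower of 17 (median -0.14, adjusted p = 0.981). The clock list had 3 genes higher, 0 lower and 10 uncalled, or 2 higher adjusted over the list alone (median 0.40, adjusted p = 0.334). The replicates of clock genes lay farther apart than those of most genes, with a median replicate SD of 0.76 against 0.11 over all genes. For every other list of this comparison the counts adjusted over the list alone were equal to those over all genes. IRT1 and PR1 were not well above background on any array and were not tested.

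In total camera called 5 lists higher and 8 lower of 20. With an estimated correlation camera called 0, while 3 had an unadjusted p under 0.05, and fry called 8 higher and 11 lower. Of 4719 changed genes with several probes, 52 had another probe called the other way.

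**Figure D1:**
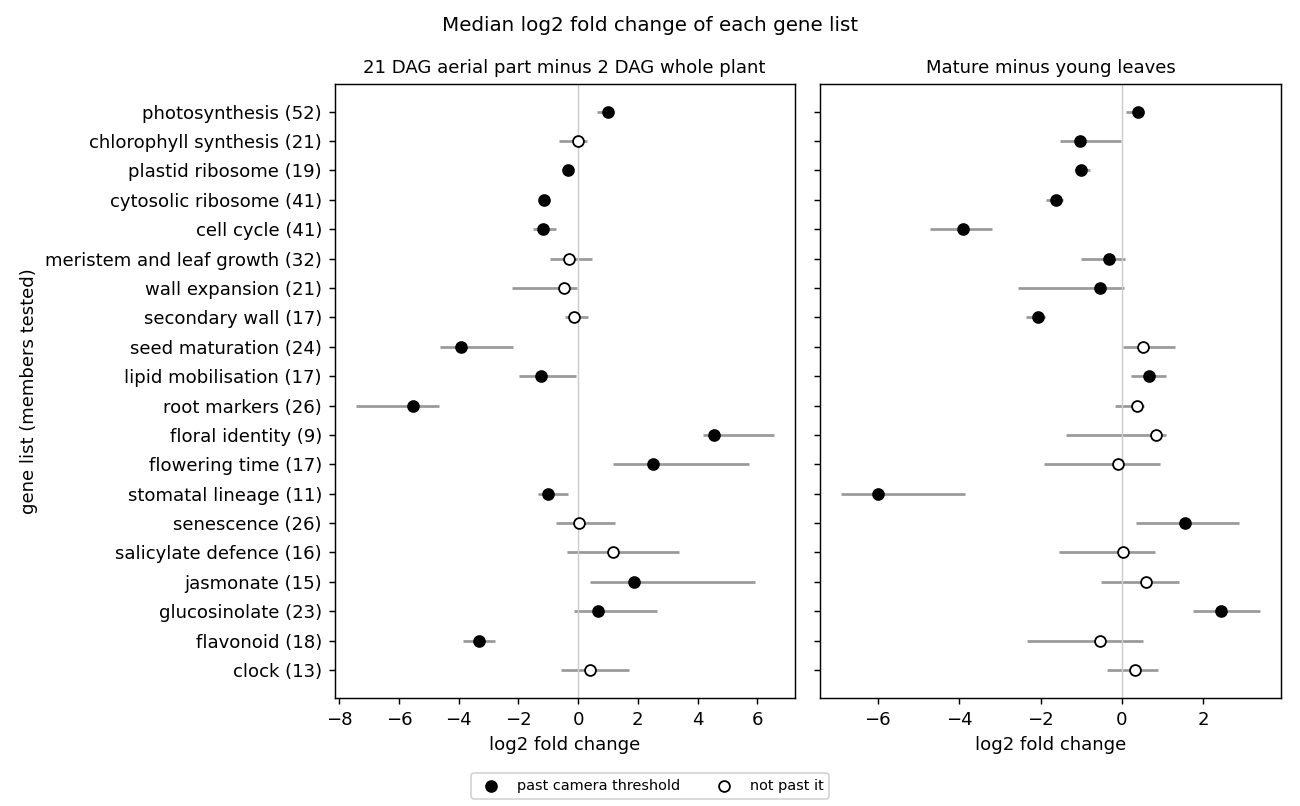
Median log2 fold change (horizontal axis) of each gene list (vertical axis, members tested in brackets) at 21 against 2 days and in mature against young leaves, with grey lines from the lower to the upper quartile and filled points past the camera threshold at a preset correlation of 0.01. Root markers at -5.51 lie lowest at 21 days, and the stomatal lineage at -5.98 and the cell cycle at -3.90 lie lowest in mature leaves, or at -4.04 and -3.82 with undetected genes at their bounds (adjusted p with an estimated correlation 0.265 for root markers and 0.174 for both others); the photosynthesis median of mature leaves, 0.39, was -0.031 under quantile normalization and -0.52 under spike-in scaling.

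The second comparison asks how mature leaves differ from young leaves of plants of the same age. The lists of the cell cycle and the stomatal lineage fell in mature leaves, with median log2 fold changes of -3.90 and -5.98, or -3.82 and -4.04 with undetected genes at their bounds. The glucosinolate list rose by a median of 2.43, and the senescence list, in which 19 of 26 genes rose and 4 fell, by a median of 1.54, or 1.19 at the bounds. With an estimated correlation between genes the adjusted p of each of these 4 lists was 0.174, above the threshold. ORE1 (AT5G39610, a NAC factor of leaf senescence) rose by 5.77 ± 0.10, a 54.7-fold increase. Ribosomal protein genes of the cytosol and the plastid fell in every member tested.

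Here 7386 genes were higher and 7319 lower in mature leaves (limma, 71.3% of 20629). Of these, 2816 and 3824 changed at least 2-fold, and 201 and 310 at least 16-fold. The 2-fold counts were 2036 and 1978 with normexp, 4024 and 2958 with median scaling, and 1088 and 9092 with spike-in scaling. Among all genes tested, 258 were detected on both arrays of mature leaves and on no array of young leaves, and the reverse held for 745. The split of all calls depends on the scaling. It was 10376 higher and 5922 lower with normexp background correction, 9878 and 5672 with median scaling, and 1831 and 14462 with spike-in scaling, under which the median of all genes moved by -0.91. The 1540 genes undetected on every leaf array had a median log2 fold change of 0.51, and 584 higher and 110 lower calls fell among them; without them 6802 genes were higher and 7209 lower.

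The largest rises among genes detected in both leaf classes were AT5G15500 (log2 fold change 7.88 ± 0.24), NAS1 (AT5G04950, nicotianamine synthase, 7.05 ± 0.32), CYP81D11 (AT3G28740, a cytochrome P450, 6.85 ± 0.22), AT1G76960 (6.79 ± 0.31) and AAP4 (AT5G63850, an amino acid transporter, 6.61 ± 0.19). The largest falls were PDF1 (AT2G42840, an epidermal protein, -9.71 ± 0.13), GER3 (AT5G20630, a germin-like protein, -9.27 ± 0.81), MLP423 (AT1G24020, -8.95 ± 0.19), AT2G33850 (-8.68 ± 0.33) and LTP6 (AT3G08770, a lipid transfer protein, -7.73 ± 0.18). PDF1 was detected in mature leaves, but its log2 level there, -6.18, was close to the lowest signal called well above background. MAM3 (AT5G23020, an enzyme of aliphatic glucosinolate synthesis) was at least 139-fold higher in mature leaves, and LTL1 (AT3G04290, a lipase-like protein) at least 942-fold lower.

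All 41 cell cycle genes fell, with a median of -3.90, or -3.82 at the bounds (camera adjusted p = 3.51e-16, and 0.174 with an estimated correlation). HIK (AT1G18370, a cytokinesis kinesin) had a log2 fold change of -6.15 ± 0.16, CYCB1;2 (AT5G06150) one of -5.95 ± 0.24, detected on 1 of 2 arrays of mature leaves, and CYCB1;1 was at least 25.4-fold lower. PCNA1 and CDKB2;1 (AT1G76540) had log2 fold changes of -4.25 ± 0.13 and -4.12 ± 0.11. The stomatal lineage fell in 10 of 11 genes and rose in 0, with a median of -5.98, or -4.04 at the bounds (camera adjusted p = 2.79e-06, and 0.174 with an estimated correlation). SDD1 (AT1G04110) was at least 111-fold, BASL at least 44.3-fold and SPCH (AT5G53210, which starts the lineage) at least 15.6-fold lower.

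The cytosolic ribosome fell in 41 of 41 genes, with a median of -1.62 (camera adjusted p = 7.32e-14, and 0.266 with an estimated correlation), and RPS6A had a log2 fold change of -2.65 ± 0.08 and RPL9D (AT4G10450) one of -2.62 ± 0.10. Plastid ribosomal proteins fell in 19 of 19 genes, with a median of -1.01 (camera adjusted p = 2.79e-06, and 0.407 with an estimated correlation). RPL9 and RPL4 (AT1G07320) had log2 fold changes of -1.54 ± 0.08 and -1.25 ± 0.08. Secondary wall genes fell in 16 of 17 and rose in 1, with a median of -2.06 (camera adjusted p = 3.80e-06, and 0.243 with an estimated correlation). XCP1 (AT4G35350, a xylem protease) had a log2 fold change of -3.18 ± 0.08, and IRX15 (AT3G50220) was at least 5.16-fold lower. Chlorophyll synthesis fell in 15 of 21 genes and rose in 1, with a median of -1.04 (camera adjusted p = 6.84e-04, and 0.174 with an estimated correlation). PORA (AT5G54190, a protochlorophyllide reductase) had a log2 fold change of -4.51 ± 0.25 and GSA1 (AT5G63570) one of -1.87 ± 0.08.

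Wall expansion fell in 11 of 21 genes and rose in 4, with a median of -0.55 (camera adjusted p = 0.0281, and 0.174 with an estimated correlation). XTH9 (AT4G03210) and XTH16 (AT3G23730), which remodel xyloglucan, had log2 fold changes of -6.28 ± 0.14 and -4.03 ± 0.15. Meristem and leaf growth regulators fell in 16 of 32 genes and rose in 4, or 15 and 4 adjusted over the list alone (3 members and 1 of the higher calls were undetected on every leaf array), with a median of -0.33, or -0.18 at the bounds (camera adjusted p = 0.0304, and 0.174 with an estimated correlation). GRF9 (AT2G45480) was at least 13.7-fold and GRF5 (AT3G13960) at least 4.70-fold lower, and ANT (AT4G37750) had a log2 fold change of -2.78 ± 0.08. AN3 (AT5G28640) was called at -0.27 ± 0.10 with an adjusted p of 0.0494, and was not called in most alternatives, median scaling (-0.010) among them. The meristem call was lost with the mean over probes, the stricter filter, the value table, spike-in scaling and normexp, where its median was 0.046, without mature replicate 1 (median -0.36) and without young replicate 1 (median -0.25). The wall expansion call was lost with the mean over probes and with spike-in scaling.

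All 23 glucosinolate genes rose, with a median of 2.43 (camera adjusted p = 1.82e-10, and 0.174 with an estimated correlation), and CYP79F2 (AT1G16400) was at least 19.8-fold higher. Senescence rose in 19 of 26 genes and fell in 4, or 21 and 4 adjusted over the list alone, with a median of 1.54, or 1.19 at the bounds (camera adjusted p = 6.84e-04, and 0.174 with an estimated correlation). Besides ORE1, ORS1 (AT3G29035) rose by 7.29 ± 0.35, detected on 1 of 2 arrays of young leaves, SEN1 (AT4G35770) by 4.72 ± 0.18, and NAP (AT1G69490) by 3.13 ± 0.43, and NYE1 (AT4G22920, of chlorophyll breakdown) rose 2.65-fold. WRKY53 (AT4G23810) was at least 10.3-fold lower. The other members that fell, BFN1, GLN1;4 and WRKY22, are named after their values were seen, and 2 of the 19 that rose were undetected on every leaf array. The late senescence gene SAG12 and the defence gene PR1 were not well above background on any array.

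Lipid mobilisation rose in 12 of 17 genes and fell in 0, with a median of 0.66 (camera adjusted p = 6.41e-04, and 0.174 with an estimated correlation), or -0.26 under spike-in scaling. MLS was at least 8.55-fold higher, and CSY3 (AT2G42790, a peroxisomal citrate synthase) rose by 1.71 ± 0.10. Photosynthesis rose in 29 of 52 genes and fell in 3, with a median of 0.39 (camera adjusted p = 0.00293, and 0.727 with an estimated correlation). This median turned to -0.031 under quantile normalization and -0.52 under spike-in scaling, and the call was also lost with normexp (0.33) and with the mean over probes (0.065). RCA (AT2G39730, Rubisco activase) rose by 0.82 ± 0.19 and LHCB1.5 (AT2G34420) by 0.80 ± 0.14, values of -0.089 and -0.11 under spike-in scaling. RBCS1A rose by 0.39 ± 0.08 on its brightest probe, while another probe was called the other way and quantile normalization gave -0.17. LHCB2.1 was not called, at -0.28 ± 0.21 (adjusted p = 0.283), though it was called as lower in 2 alternatives chosen after seeing the data, spike-in scaling among them.

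The remaining lists did not pass the camera test in leaves, though seed maturation and root markers passed with normexp (medians 0.70 and 0.65), and seed maturation (-0.39), the clock (-0.60) and jasmonate (-0.32) passed with spike-in scaling. Camera, which sets a list against all other genes, pointed upward there although these medians were negative. Jasmonate had 9 genes higher and 4 lower of 15 (median 0.59, adjusted p = 0.254). Seed maturation had 9 higher and 2 lower of 24, or 8 and 2 adjusted over the list alone (median 0.52, or 0 at the bounds, adjusted p = 0.208). Genes undetected in both leaf classes count as 0 at the bounds. Of the seed genes 14 were undetected on every leaf array, and 4 of the calls fell among them. Flavonoids had 7 higher and 8 lower of 18, with 2 and 1 of these undetected on every leaf array (median -0.54, or 0 at the bounds, adjusted p = 0.355). Salicylate defence had 5 and 5 of 16 (median 0.03, or 0.06 at the bounds, adjusted p = 0.721). Floral identity had 5 and 3 of 9 (median 0.84, or 0.65 at the bounds, adjusted p = 0.538). Root markers had 7 higher and 4 lower of 26, or 6 and 4 adjusted over the list alone (median 0.36, or 0 at the bounds, adjusted p = 0.474). Of these calls, 4 of the higher and 1 of the lower were on genes undetected on every leaf array. Flowering time had 8 higher and 7 lower of 17, with a median of -0.09, or 0 at the bounds, where camera pointed upward (adjusted p = 0.872). The clock had 2 genes higher and 0 lower of 13, or 1 and 0 adjusted over the list alone (median 0.31, adjusted p = 0.538).

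Where no other count is given for leaves, the count adjusted over the list alone was equal. Camera called 4 lists higher and 8 lower of 20. With an estimated correlation camera called 0, while 5 had an unadjusted p under 0.05, and fry called 6 higher and 9 lower. Of 4574 changed genes with several probes, 112 had another probe called the other way.

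**Figure D2:**
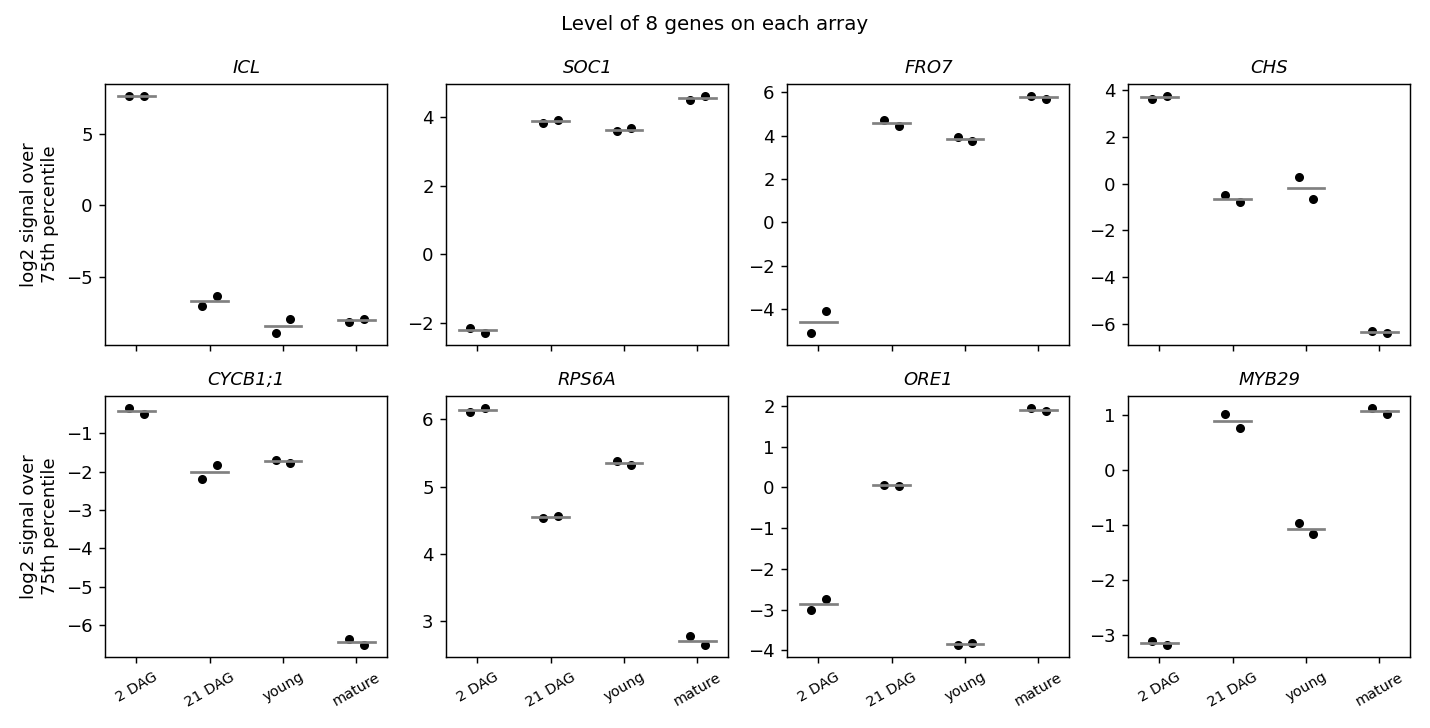
Level of 8 genes on each array (points) and as group means (grey lines), as log2 signal relative to the 75th percentile of the array (vertical axis), in the 2-day whole plant, the 21-day aerial part, young leaves and mature leaves (horizontal axis). ICL drops from 7.65 at 2 days to -6.64 at 21 days, and ORE1 climbs from -3.86 in young to 1.92 in mature leaves. ICL in both leaf classes and CYCB1;1 in mature leaves were not well above background.

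Set side by side, the 2 main comparisons share no array, and across 20629 genes their log2 fold changes correlated at a Pearson r of 0.152 and a Spearman rho of 0.296, with the same sign in 65.0% of genes. Higher in both were 4082 genes, against 2573 if the calls were independent, and lower in both were 4350, against 2948. Called higher at 21 days and lower in mature leaves were 1264 against 2549, and the reverse held for 1780 against 2975. The largest of the 4 Fisher's exact p-values was 2.67e-284, computed across genes, which are not independent replicates. The lipid mobilisation list fell at 21 days in 12 of 17 genes and rose in mature leaves in 12, and the difference between the comparisons had a median of 2.13 (camera adjusted p = 1.53e-05, and 0.182 with an estimated correlation).

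The secondary contrast asks which transcripts of the aerial part at 21 days lie away from the mean of the leaf classes. DR4 (AT1G73330) was higher by 6.19 ± 0.28 on the log2 scale, CYP81F4 (AT4G37410, of indole glucosinolate synthesis) by 5.97 ± 0.25, AT4G29030 by 5.34 ± 0.10, MLP328 (AT2G01520) by 5.27 ± 0.22 and TT19 (AT5G17220, of anthocyanin transport) by 5.04 ± 0.21. All these except AT4G29030 lay among the genes most raised over each leaf class. AT4G29030 was 1.60 ± 0.12 above young and 9.08 ± 0.12 above mature leaves, so its value stems mostly from the low level in mature leaves, and against the mean of linear signals it was higher by 2.59 ± 0.10. Calls were 3568 higher and 869 lower (limma, 21.5% of 20629), and 1779 and 21 of at least 2-fold. Of the higher calls 97 were on genes undetected in the aerial part, and of the lower calls 194 on genes undetected on every leaf array. The aerial part and the leaves were on different slides, so slide and group cannot be told apart in this contrast.

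The lower count and the split move with the processing. Calls were 2279 higher and 2211 lower with normexp, 2784 and 1529 with quantile normalization, 2776 and 9211 with median scaling, 2702 and 200 with the value table, 6113 and 31 with spike-in scaling, and 3715 and 2961 with no filter on dim probes. Single arrays matter as well: calls were 2293 and 78 without aerial replicate 1 and 2297 and 77 without replicate 2, and the lower count was 329 and 198 without young replicate 1 or 2, and 424 and 558 without mature replicate 1 or 2. The 2-fold counts were 326 and 0 with normexp, 657 and 0 with only probes well above background on all arrays, and 843 and 1 with the value table.

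Of the 3568 higher calls, 1890 had a level in the aerial part between those of the leaf classes. Above both leaf classes, each tested on its own, were 1044 genes, and below both 103, of which 686 and 5 by at least 2-fold. These counts move too, to 499 and 129 with normexp, 801 and 1770 with median scaling, 770 and 400 with quantile normalization, 527 and 34 with the value table and 1212 and 7 with spike-in scaling. With only probes well above background on all arrays they were 425 and 103, and without aerial replicate 1 or 2 they were 828 and 33 or 881 and 29. Without young replicate 1 or 2 the count below both was 50 or 41, and without mature replicate 1 or 2 it was 49 or 68. Of the 1044, 65 were undetected on both arrays of the aerial part, and of the 103, 15 were undetected on every leaf array.

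Camera called 10 lists higher and 3 lower in the aerial part. The cell cycle was higher in 38 of 41 genes (median 1.49), the stomatal lineage in 9 of 11 (9, with 1 lower, adjusted over the list alone), floral identity in 6 of 9 (median 2.51, or 7 adjusted over the list alone), the secondary wall in 13 of 17 (median 0.70) and wall expansion in 12 of 21 (median 0.87). Higher were also 15 of 32 meristem and leaf growth genes (19, with 1 lower, adjusted over the list alone), 13 of 18 flavonoid genes with 2 lower, 13 of 23 glucosinolate genes with 1 lower (16 and 1 adjusted over the list alone), 16 of 41 cytosolic ribosome genes (30 adjusted over the list alone) and 9 of 17 flowering time genes (10 adjusted over the list alone). Photosynthesis, chlorophyll synthesis and plastid ribosomal proteins had medians of -0.18, -0.17 and -0.09, with 2, 2 and 1 genes lower, or 0, 2 and 0 adjusted over the list alone, and 0, 1 and 0 higher. The chlorophyll gene that was higher is PORA, named here after its value was seen. The adjusted p with an estimated correlation was 0.116 or more for every list. With it camera called 0 lists, while 5 had an unadjusted p under 0.05, and fry called 15 higher and 2 lower.

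Several of these calls depend on how the leaf classes are averaged. Against the mean of linear signals, a reference chosen after seeing the data, camera called 6 lists higher and 3 lower (with an estimated correlation 0, smallest adjusted p = 0.133, while 2 had an unadjusted p under 0.05). The cytosolic ribosome (adjusted p = 0.152), the stomatal lineage (0.649), glucosinolates (0.649) and flowering time (0.0550) were not called. Of the secondary wall genes 11 of 17 were lower than in young leaves and 15 higher than in mature leaves, and 2 were higher against the mean of linear signals (median 0.35). Lower than in young leaves were also 40 of 41 cytosolic ribosome genes, all 11 of the stomatal lineage and 22 of 41 cell cycle genes. Against the mean of linear signals 18 cell cycle and 7 of 21 wall expansion genes were higher.

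Above both leaf classes were 10 of 32 meristem genes, 8 of 18 flavonoid genes, 5 of 26 root markers and 4 of 9 floral identity genes. Wall expansion had 3 of 21 there, seed maturation 3 of 24 and flowering time 3 of 17. Lipid mobilisation, salicylate defence and jasmonate had 1 gene each, of 17, 16 and 15. None were in the cell cycle (0 of 41), the cytosolic ribosome (0 of 41), the secondary wall (0 of 17), the stomatal lineage (0 of 11) or the glucosinolate list (0 of 23). Of the 5 root markers, 2 were undetected on both arrays of the aerial part, and 0 of the genes of the other lists were. The remaining root markers, WER, PHT1;1 and PYK10, named after their values were seen, were well above background on both aerial arrays. PYK10 was 4.81 ± 0.19 above young and 4.34 ± 0.19 above mature leaves, and which tissue these transcripts came from was not tested. Named after their values were seen, the meristem genes STM (AT1G62360) and KNAT1 (AT4G08150) were well above background on both arrays of the aerial part and on no leaf array.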

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

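The tests on the spike-in probes, the scaling of the arrays, the time of day at harvest, the loss of the root, the averaging of log values, floral tissue and the iron-deficiency response were chosen only after the patterns were seen; for the last 3, what would speak for or against was written before the test was run.

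Lipid mobilisation genes moved opposite ways in the main comparisons, and the difference itself, tested in the same fit, had a median of 2.127 (camera adjusted p = 1.53e-05, and 0.182 with an estimated correlation). With spike-in scaling the median of lipid mobilisation in mature leaves was -0.26, and the medians no longer ran opposite ways. Outside the genes reported on, 4576 probes without a locus were well above background on both arrays of at least 1 group, and 1677 of them were higher and 1240 lower at 21 days. In mature leaves 1612 of these probes were higher and 1170 lower.

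Iron-related genes stood among the largest rises at 21 days: FRO7, FRO6 and the small-peptide loci AT1G47400 and AT1G47395 had a median log2 fold change of 8.20. Loss of the root from the sample is argued against as the whole source. Photosynthesis genes, which roots barely express, rose by a median of 1.005, a value that holds their own change with age as well. An iron-deficiency response of the older plants may be the source: 12 other genes of that response, written down after the pattern was seen, had a median of 2.994 with 9 higher and 3 lower, and the 3 ferritin genes fell, with a median of -4.09. Not all of the 12 are regulators: OPT3, FRO3 and NAS4, for example, are not, and FRO3 is of the family of FRO6 and FRO7. Nor did the 4 genes of the pattern move together: in mature against young leaves FRO7 and FRO6 rose, and AT1G47400 and AT1G47395 fell. Another time of day at harvest stays open, since the clock list had a median absolute change of 0.7998 and its replicates lay far apart. Age and organ cannot be separated by this design, and iron levels are not used here.

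In mature leaves the 75th percentile of probes was lower against the spike-in probes than in young leaves, by -0.91 on the log2 scale. A dimmer array as a whole is argued against, because the spike-in probes themselves were brighter by 0.1432. A few genes taking most of the signal would leave the total signal level, but the total over the spike-ins changed by -0.7133. Less messenger RNA per total RNA in mature leaves could account for it, since without the 100 brightest probes the total still changed by -0.8298; the spike-in dose per array is not stated, which keeps this open. Counts of higher and lower genes in mature leaves are therefore relative to the bulk of transcripts.

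More genes were higher than lower in the aerial part against the mean of the leaf classes. Averaging log values of unlike leaf classes is argued against as the whole source only for an equal mix of the classes at the 75th percentile scaling. Against that mean of the linear signals 73.94% of calls were still higher, 1671 against 589. Other mixes were not run, so the test cannot exclude averaging in general. Much of the higher count does depend on it: the higher calls fell from 3568 to 1671, and 1890 of the 3568 lay between the leaf classes. The scaling of the arrays stays open: over the other scalings the share of calls that were higher ran from 23.16%, with median scaling, to 99.5%, with spike-in scaling. Floral tissue in the aerial part may contribute and stays open, as 44.44% of the floral identity list, 4 of 9 genes, lay above both leaf classes. Slide and group cannot be told apart here, and the stem and the other leaves of the aerial part are biological differences that the design names and that were not tested.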

How the results depend on the processing

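The alternatives with spike-in scaling, with the mean of linear signals and with a block over the 21-day groups were chosen only after the result was seen; all others were planned. Among planned and added alternatives that leave out no array, 1140 values of named genes kept their direction and side of the threshold, 20 lost their call, 2 gained it and 6 reversed; for the medians of lists these counts were 469, 37, 15 and 7, where a change in the sign of a called median is a reversal. Causes were not tested unless given.

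For the gene counts with age and in leaves, no alternative but a fold of at least 2 as well and spike-in scaling moved a count by over 1.5 times. A fold of at least 2 asks more by construction and left 3104 higher and 4361 lower with age, 2816 and 3824 in leaves, and 1779 and 21 in the aerial contrast. Spike-in scaling gave 4406 higher with age, 1831 higher and 14462 lower in mature leaves, and 6113 and 31 in the aerial contrast, and moved the median of all genes by -0.29, -0.91 and 0.28. It also reversed the medians of photosynthesis (-0.52), seed maturation (-0.39), lipid mobilisation (-0.26), jasmonate (-0.32) and the clock (-0.60), and RBCS1A (-0.52), LHCB1.5 (-0.11) and RCA (-0.089) in mature leaves. Normexp reversed the median of meristem and leaf growth in leaves (0.046). Normexp, median scaling and no filter on dim probes (other genes tested) moved the median of all genes by 0.18, 0.26 and 0.18 in leaves, median scaling by -0.25 in the aerial contrast, and no filter and the value table by 0.11 each with age. Quantile normalization reversed RBCS1A with age (-0.10), and RBCS1A (-0.17) and the photosynthesis median (-0.031) in mature leaves; the mean over probes reversed RBCS1A there (-0.16).

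The aerial contrast moved most: 2279 higher and 2211 lower with normexp, 1529 lower with quantile normalization, 9211 lower with median scaling, 2961 lower with no filter on dim probes, 2310 higher with probes well above background on all arrays (fewer genes tested), 200 lower with the value table, and 1671 higher against the mean of linear signals. Leaving out 1 array at a time, its higher count ranged from 2293 to 3492 and its lower count from 77 to 1156. The lowest values came without 21 DAG aerial part replicate 1 (2293 and 78) or replicate 2 (2297 and 77), and the lower count was 329, 198, 424 and 558 without each young and then each mature array. The lone array left in a group is assumed to vary like the others.

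Counts of at least 2-fold moved by over 1.5 times with normexp (2776 lower against 4361 with age, 1978 lower against 3824 in leaves, 326 and 0 against 1779 and 21 in the aerial contrast) and with probes well above background on all arrays (2271 lower with age, 657 and 0 in the aerial contrast). Spike-in scaling gave 1088 and 9092 in leaves, against 2816 and 3824. In the aerial contrast the value table gave 843 and 1, and the lower count was 76 with quantile normalization, 60 with median scaling, 58 with no filter, 9 with spike-in scaling, and 33 and 46 without mature replicate 1 or 2. The genes above and below both leaf classes, 1044 and 103, were tested over the alternatives only after the result was seen: normexp gave 499 above, 441 of them among the 1044, quantile normalization 400 below, median scaling 1770 below, spike-in scaling 7 below, and the stricter filter 425 above. The value table gave 527 and 34. Leaving out 1 array gave 828 to 1046 above and 29 to 132 below.

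With an estimated correlation, camera called 0 lists up and 0 down with age and 0 and 0 in leaves, while 3 and 5 lists had an unadjusted p under 0.05; fry called 8 up and 11 down with age. A slide block was not run, because each slide holds whole groups. A fold threshold does not apply to lists or to the correlation.

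The labels give no source for the replicate numbers. Deviations of arrays sharing a number correlated at -0.06 between the age groups, but at 0.25 between the leaf classes, and at 0.35 and 0.31 between the aerial part and young and mature leaves, a hint from the data, not the design, that numbers pair the 21-day groups. With a replicate block over all arrays, calls were 7335 and 8413, 7587 and 7476, and 3722 and 956, and no call of a list or named gene changed. With the replicate block over the 6 arrays of the 21-day groups alone, calls were 8017 and 7814 in leaves and 4123 and 1949 in the aerial contrast, against 3421 and 1156 on these arrays without it, with 1120 genes above and 257 below both leaf classes, and LHCB2.1 gained a call in leaves (-0.28); no other call of a list or named gene changed. Signal limits dim genes: those not well above background on a group's arrays have only a bounded fold.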

Other observations

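The groups by symbol, the lists of cold-regulated and iron-related genes and the tests of replicate spread were chosen only after the result was seen; the clock and jasmonate lists were not.

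Genes grouped by the stem of their symbol, 137 groups of at least 10 members, showed further shifts. At 21 days 12 of 13 SPL genes rose, with a median log2 fold change of 1.77 (camera adjusted p = 4.41e-04). Some SPL genes promote phase change, and several are in the flowering time list. Of 14 SAUR genes, which respond to auxin, 13 rose, with a median of 2.11. XTH genes of wall remodelling fell in 23 of 28, with a median of -2.22, and heat shock HSP genes in 17 of 22, with a median of -1.70. In mature leaves 14 of 16 autophagy ATG genes rose, with a median of 0.66, and 17 of 21 CIPK kinases, with a median of 1.25. Arabinogalactan AGP and FLA genes fell there in 21 of 26 and 13 of 15, with medians of -2.02 and -2.29, KCS genes of wax and cuticle lipids in 13 of 17, and embryo-defective EMB genes in 97 of 143. Camera at the preset correlation called 8 groups up and 14 down with age, and 7 and 12 in leaves; with an estimated correlation it called 0 in each, and the adjusted p was 0.661 or 0.543 for the groups named.

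Of 10 cold-regulated genes, written down after COR15A was seen, 5 rose at 21 days with a median of 1.38, and 6 rose in mature leaves with a median of 1.53. Over all 20629 genes, 7185 and 7386 rose in these comparisons. The regulators DREB1A, CBF1 and CBF2, which lie outside the rule for named genes, were higher by 5.27 ± 0.27, 3.73 ± 0.20 and 2.36 ± 0.21 at 21 days. KIN1, LTI78, COR47, LTI30 and GOLS3 were not called there.

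The clock list had a median replicate SD of 0.76 on the log2 scale, and 0 of 10000 random lists of the same size and signal level reached it, the highest being 0.22. In the 21-day aerial part, young leaves and mature leaves, the second array minus the first was -1.43, -2.19 and -1.41 for LHY, a gene that peaks near dawn, and 1.41, 1.49 and 1.15 for TOC1, a gene that peaks in the evening. In the 2-day plants these differences were 0.19 and -0.10. LHY and TOC1 lie outside the rule for named genes. The jasmonate list had a median replicate SD of 0.25, which 1 of 10000 random lists reached.

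The 12 tested genes of the iron-deficiency response had 1 gene higher and 6 lower in mature against young leaves, with a median of -0.21. The 4 genes the pattern was seen in split there: FRO7 and FRO6 rose by 1.91 ± 0.32 and 2.04 ± 0.13. AT1G47400 and AT1G47395 had log2 fold changes of -1.73 ± 0.22 and -1.79 ± 0.30.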
